A study of Mus musculus with 4 samples.

How the data were processed

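Total RNA of lung tissue from 2 WT and 2 SA mice was made into strand-specific libraries after removal of ribosomal RNA, per the labels' protocols. Subread, featureCounts and limma and the build GRCm38 are named in the submitters' processing notes, without versions or settings; the annotation release is not given in the sources used here. The deposited files are 2 tables of log2 values, one filtered and one unfiltered. From the values, each log2 value equals the log2 of CPM computed from a read count with 0.5 added, divided by the library's total with 1 added. Undoing this gave whole reads for 100.0% of genes in every library, within 0.001 read, and the reads summed to the totals. No further scaling factor is in the deposited log2 values. Tests were run on the log2 values as deposited.

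The filtered table has 13041 lines for 12850 Ensembl genes and the unfiltered one has 47511 lines for 46603; repeated identifiers hold equal values and were kept once, and the largest difference between the tables for a gene is 0. The rule of the deposited filter is not given in the sources used here. Of the 33753 genes left out, 0 have 2 libraries at 10 CPM or more, while 2110 of the genes kept do not have 2 such libraries, 480 are under 1 CPM in every library and 67 have 0 reads in all 4. Names, biotypes and positions came from GENCODE M21 on GRCm38, in which 12822 of the 12850 identifiers were found.

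The totals of 27381916 to 38378936 gene reads put 3 reads, used as the detection floor, at 0.078 to 0.11 CPM. Reads without molecular identifiers are not independent molecules, so this floor covers counting error only. Each pair of libraries differed by far more than sampling noise (chi-square per degree of freedom of 51.4 or more), so the 4 columns are 4 different libraries. This does not show that the libraries came from separate animals. The series' design text calls the samples biological replicates and the labels do not number the animals, so p-values measure the spread between these samples. With 2 libraries in each group no permutation of the samples can give a p under 0.05, and all p-values rest on the limma model.

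SA was compared with WT in limma 3.58.1 (R 4.3.3) on the filtered table with genotype as the only term, lmFit and eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over 12850 genes and a threshold of 0.05. There were 2 residual degrees of freedom and 2.25 prior degrees of freedom. Before the data were examined, 45 gene lists with 920 entries were fixed from textbook knowledge. The 42 lists with at least 5 measured genes were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over the 42; camera with an estimated correlation and fry were run beside it. Per-gene calls were also adjusted over each list alone.

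The named genes also followed a rule fixed at that time. They are Ifnar1; Cxcl1, Cxcl2, Cxcl3, Cxcl5, Cxcl15, S100a8, S100a9, Ch25h, Fn1, Fap and Mmp9 whatever their result; the 12 largest rises and the 12 largest falls among genes past the threshold with separated groups and a mean of at least 1 log2 CPM, leaving out unnamed gene models, pseudogenes and immunoglobulin or T cell receptor segments; and up to 4 genes with the lowest p of each list described. Genes outside the rule are said to be so where they appear.

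The alternatives fixed with the lists were the replicate number as a block, the unfiltered table, a filter at a mean of 1 log2 CPM, median centring, quantile normalization, leaving out each library, no trend, a robust trend, another pseudocount, and the other list tests. After the data were seen, voom on the recovered reads (with library totals and with median-of-ratios scaling), the unfiltered table at a mean of at least 1, and a muscle score as a covariate were added. Count models planned for recovered reads were not run, although whole reads had been recovered, and voom on those reads was added instead.

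The test was checked on simulated libraries with the real means and totals, 20 times, with 200 genes changed among 12850. With the spread drawn from the fitted prior, 57.9% of the 100 genes changed by 1 log2 unit and 89.8% of the 100 changed by 2 were recovered, and 5.52% of calls were false. With each gene's own moderated variance these were 80.2%, 96.7% and 8.64%. A list of 26 genes raised by 0.5 was found by camera in 20 of the 20 simulations, and 0 and 11 of 820 tests of the other lists passed with these 2 kinds of spread. The simulated genes are independent, so correlated genes were not tested in this way. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the remaining steps.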

Results

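Lung RNA was sequenced in 4 samples from mice of the C57BL/6 background. The WT group of 2 samples had the normal Ifnar1 gene, and the SA group of 2 samples had the Ifnar1 S526A allele, in which a serine of this chain of the type I interferon receptor is replaced by alanine. The mice were littermates aged 6 to 8 weeks. All of them received intravenous injections of 100 µl of medium conditioned by B16F10 cells, a mouse melanoma line, 3 times a week for 3 weeks. Untreated mice were not analysed here, so each comparison is between genotypes under conditioned medium. The libraries held 30611946 gene reads in WT 1, 31645038 in WT 2, 27381916 in SA 1 and 38378936 in SA 2. The series title concerns loss of IFNAR1 caused by tumour-derived factors and the production of chemokines that attract neutrophils. The comparison of SA with WT lungs addresses the chemokines at the level of mRNA. All samples received the medium and receptor protein was not measured, so the loss of IFNAR1 itself was not tested. Values are on the log2 CPM scale, in which each gene's read count is scaled to the total of its library, and are given as mean ± SD with n = 2 per group. Differences are SA minus WT on the log2 scale, with the standard error (SE) of the limma fit.

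Ifnar1 mRNA did not differ detectably between the 2 genotypes. This gene (ENSMUSG00000022967) lies on the plus strand of chromosome 16 from 91485238 to 91507441 in GRCm38. Its log2 CPM was 6.09 in WT 1, 6.14 in WT 2, 6.22 in SA 1 and 6.03 in SA 2. The difference was 0.01 ± 0.08 (SE), with a 95% interval from -0.21 to 0.24 and an adjusted p of 0.93 (limma, Benjamini-Hochberg). A single amino acid change need not alter the mRNA level, so this value does not check the genotype labels. Its sign changed when SA 1 was left out (-0.0815), when WT 1 was left out (-0.0130) and with median centring (-0.0347).

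Genes induced by type I interferon rose in the SA lungs. The median difference over the 47 measured genes of this list was 0.91, and 45 of them were higher in SA. Over all genes tested, 10 of the 47 passed the threshold, all upward; adjusted over the list alone, 44 rose and 1, Helz2 (-0.34), named after its value was seen, fell. Irf7, a transcription factor of the interferon response, rose by 1.88 ± 0.06 (SE; adjusted p = 0.025), from 4.04 ± 0.01 to 5.92 ± 0.01 log2 CPM. Oasl2, of the oligoadenylate synthetase family, rose by 1.40 ± 0.06 (adjusted p = 0.029). Ifit1, an antiviral RNA-binding protein, rose by 1.89 ± 0.09 (adjusted p = 0.032), and Usp18, a negative regulator of interferon receptor signalling, rose 2.82-fold from 4.23 ± 0.10 to 5.73 ± 0.02 (adjusted p = 0.033). Oas2, Oas1a, Ifi44 and Zbp1 rose by 2.55, 1.95, 1.78 and 1.74, and Apol9b, which is outside the list, by 2.68. Reads of Oas1a and of Apol9b can be shared with close paralogs. The list's mean level was 4.18 in WT 1, 4.14 in WT 2, 5.26 in SA 1 and 5.23 in SA 2, while muscle genes, described further on, were higher in WT 2 than in WT 1. Camera with a preset correlation gave an adjusted p of 9.3e-21 for the list; with an estimated correlation the call was lost (adjusted p = 0.60), as it was in fry (adjusted p = 0.052).

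**Figure D1:**
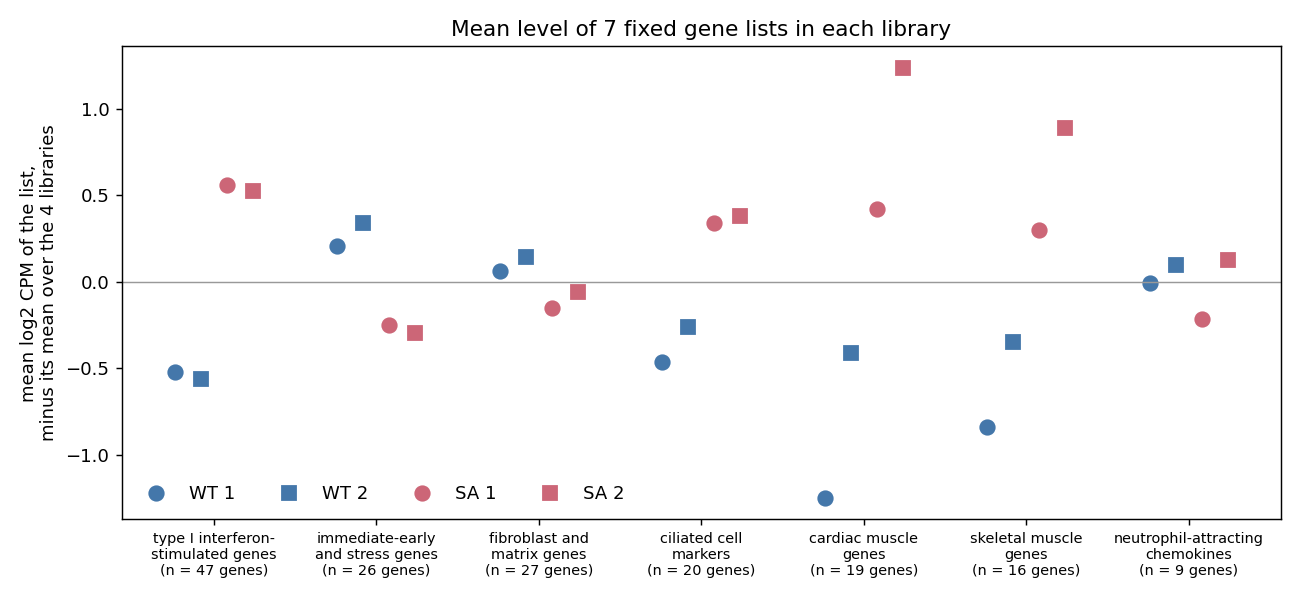
Mean log2 CPM of 7 fixed gene lists in each library, minus the mean of the 4 libraries; blue is WT and red SA, circles are replicate 1 and squares replicate 2, and the number of measured genes stands under each list. The interferon list lies at 5.26 and 5.23 in SA against 4.18 and 4.14 in WT before centring, while the cardiac muscle list also differs within each genotype, at 4.70 and 5.53 in WT and 6.37 and 7.18 in SA.

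Genes on the lists for MHC class I antigen presentation and for type II interferon rose as well. Which type of interferon, if any, lay behind this was not tested. Ifng, the type II interferon gene, had 1 to 5 reads per library. The MHC class I list had a median difference of 0.60 over 16 genes, with 2 past the threshold over all genes and 13 adjusted over the list alone. Those 2 were H2-T22, at 0.95 ± 0.07 (SE; adjusted p = 0.043), and H2-Q6, at 0.90 ± 0.07 (adjusted p = 0.043), and reads of these genes can be shared with other MHC class I genes. H2-T23 and H2-Q7 differed by 0.76 and 0.78. The MHC class II list did not pass (median 0.07 over 9 genes, 5 higher and 4 lower, camera adjusted p = 0.87). The type II interferon list had a median of 0.69 over 20 genes, of which 0 passed over all genes by limma (14 at an unadjusted p under 0.05) and 14 rose adjusted over the list alone. Of the 20, 16 were also higher in WT 2 than in WT 1 (median 0.20) and 8 in SA 2 than in SA 1 (median -0.0679), and the median difference was 0.56 without WT 1. Tgtp1, Gbp3, Igtp and Iigp1, which encode interferon-inducible GTPases, differed by 1.96, 1.02, 0.93 and 1.43. Camera gave adjusted p-values of 3.9e-07 and 1.1e-07 for these lists; with an estimated correlation the adjusted p was 0.75 for each.

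The chemokines that attract neutrophils showed no detectable difference. The list of 9 measured genes, which also holds Il1b and the receptor gene Cxcr2, had a median difference of -0.14 (camera adjusted p = 0.39). By limma 0 of the 9 passed over all genes, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. Cxcl15, an abundant lung chemokine, was at 10.53 ± 0.35 in WT and 10.12 ± 0.07 in SA, a difference of -0.41 ± 0.20 (SE; adjusted p = 0.27) that was -0.16 without WT 1 and -0.65 without WT 2. Il1b differed by -0.33 and Pf4, a platelet chemokine, by 0.23. Cxcl1 differed by -0.45 ± 0.47 on 30 to 74 reads per library. Cxcl2 differed by -0.37 ± 0.44 and Cxcl5 by 0.25 ± 0.66 on at most 27 reads per library, and Cxcl3 by 0.40 ± 0.48 on 3 to 8 reads, so that the depth would not show a moderate change in these 3. The list of 21 neutrophil markers had a median of 0.06 and did not pass camera. The neutrophil genes S100a8 and S100a9 differed by -0.01 ± 0.25 and 0.17 ± 0.20, and the protease gene Mmp9 by -0.36 ± 0.29. The median of the list turned positive without SA 1 (0.16) and without WT 2 (0.04), and Cxcl1, Cxcl2, Cxcl5, S100a8, S100a9 and Mmp9 changed sign with 1 library left out.

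Immediate-early and stress genes fell in the SA lungs. The median difference was -0.56 over 26 measured genes, of which 20 were lower in SA. Over all genes 2 of them passed, and adjusted over the list alone 15 fell and 0 rose. Nr4a1, an orphan nuclear receptor, fell by 1.49 ± 0.06 (SE; adjusted p = 0.028), from 5.89 ± 0.01 to 4.40 ± 0.02. Dusp1, a phosphatase that inactivates MAP kinases such as p38, fell by 1.05 ± 0.07 (adjusted p = 0.041). Zfp36, which destabilises cytokine mRNAs, and Klf2 differed by -0.74 and -0.91 (adjusted p = 0.0502 for each, just above the threshold). Among other genes past the threshold, the growth factor gene Areg fell by 1.37, Spry4, an inhibitor of receptor tyrosine kinase signalling, by 1.14, and Arid5a by 1.20. The list passed camera at an adjusted p of 3.7e-09 (adjusted p = 0.60 with an estimated correlation). The p38 pathway list of 18 genes did not pass (median -0.00324, camera adjusted p = 0.22), and Dusp1 was its 1 gene past the threshold.

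Matrix and vascular genes were lower in SA. The fibroblast and matrix list had a median difference of -0.32 over 27 genes, and adjusted over the list alone 15 fell and 0 rose. Over all genes 0 of the 27 passed by limma, with 15 at an unadjusted p under 0.05. Loxl1, Fbn1, Col1a1 and Npnt differed by -0.60, -0.53, -0.61 and -0.71. Outside the list, the metalloprotease genes Adamts9 and Adamts15 fell by 1.79 ± 0.09 (SE; adjusted p = 0.033) and 0.90 ± 0.07 (adjusted p = 0.048). Fn1, which encodes fibronectin, differed by -0.60 ± 0.17 (adjusted p = 0.13). It passed in the unfiltered table (limma adjusted p = 0.0072) and with the replicate number as a block. The lung endothelial list had a median of -0.27 over 23 genes, with 5 lower adjusted over the list alone and 0 past the threshold over all genes by limma (1 higher and 11 lower at an unadjusted p under 0.05). Prx, Esam and Eng differed by -0.65, -0.62 and -0.62, and Cldn5, a tight junction gene, was at 9.27 ± 0.25 in WT and 8.27 ± 0.19 in SA. The endothelial list was also lower in WT 2 than in WT 1 and in SA 2 than in SA 1, by medians of -0.21 and -0.23, and with a muscle score as a covariate it did not pass camera (median 0.17, adjusted p = 0.25). Its mean level was 7.41 in WT 1, 7.23 in WT 2, 7.15 in SA 1 and 6.90 in SA 2, and its median difference was -0.42 without SA 1. The pre-metastatic niche list had a median of -0.22 over 21 genes; Thbs1, Lox and Flt1, at -1.19, -0.63 and -0.52, fell adjusted over the list alone, Tgfb1 differed by -0.49, and over all genes 0 passed by limma (1 higher and 6 lower at an unadjusted p under 0.05). Camera gave adjusted p-values of 7.4e-07, 4.0e-06 and 0.0012 for these 3 lists (adjusted p = 0.60, 0.80 and 0.60 with an estimated correlation). Of the other genes fixed for naming, Ch25h and Fap are outside the filtered table; in the unfiltered table they differed by -0.21 ± 0.17 (adjusted p = 0.72) and 0.97 ± 0.35 (adjusted p = 0.15). Fap was at 1.35 without SA 1 and 1.56 without WT 2, and it passed with the replicate number as a block. Ch25h was at -0.40 without SA 1 and -0.0278 without SA 2.

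Muscle and ciliated cell genes were higher in SA, and both groups of genes also differed within a genotype. The cardiac muscle list had a median difference of 1.74 over 19 genes, of which 1 passed over all genes and 19 rose adjusted over the list alone. The 1 was Myh7, a cardiac myosin heavy chain, at 1.95 ± 0.12 (SE; adjusted p = 0.041); Sln, Myl3 and Myl7 differed by 1.86, 1.14 and 1.83. The skeletal muscle list had a median of 1.19 over 16 genes, with 13 higher adjusted over the list alone and 0 past the threshold over all genes by limma (13 at an unadjusted p under 0.05), and Myh2, Tnni2, Acta1 and Mylpf differed by 1.35, 1.36, 1.15 and 1.15. Of the 35 muscle genes, 33 were higher in WT 2 than in WT 1 and in SA 2 than in SA 1, with median steps of 0.71 and 0.66. Myh7 was lower in both steps. The ciliated cell list had a median of 0.82 over 20 genes, with 18 higher adjusted over the list alone and 0 over all genes (18 at an unadjusted p under 0.05), and Dynlrb2, Tekt1, Tmem212 and Ccdc153 differed by 0.82, 0.86, 0.86 and 0.78; with the muscle score as a covariate the median was 0.52. Of the 20 ciliated cell genes, 17 were higher in WT 2 than in WT 1 (median 0.22) and 13 in SA 2 than in SA 1 (median 0.02). Camera gave adjusted p-values of 8.3e-07, 1.5e-06 and 2.6e-09 for the cardiac, skeletal and ciliated lists (adjusted p = 0.80, 0.80 and 0.75 with an estimated correlation).

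A further 6 lists passed camera. Nuclear genes of oxidative phosphorylation (median 0.34, 25 of 25 higher, among them Ndufa2 at 0.29 and Atp5e at 0.37) and cytosolic ribosomal protein genes (median 0.17, among them Rpl41 at 0.21) passed camera upward, at adjusted p-values of 0.00014 and 0.0017 (adjusted p = 0.87 and 0.75 with an estimated correlation). The size of the oxidative phosphorylation difference leans on SA 2. Its mean level was 6.01 in WT 1, 6.14 in WT 2, 6.25 in SA 1 and 6.63 in SA 2, and its median difference was 0.55 without SA 1. Glucocorticoid-induced genes passed camera downward (median -0.31, adjusted p = 0.00055, and 0.75 with an estimated correlation). Dusp1, Errfi1, Per1 and Cdkn1a were at -1.05, -0.85, -0.72 and -1.15, and Dusp1 is also on the immediate-early list. Of the 14 genes of the glucocorticoid list, 11 were lower in SA. The 3 higher ones, named after their values were seen, were Tsc22d3, Fkbp5 and Pdk4 at 0.15, 0.15 and 0.79. In this list 8 genes were higher in WT 2 than in WT 1 (median 0.09) and 12 in SA 2 than in SA 1 (median 0.26). Its median difference was -0.15 without SA 1 and -0.44 without SA 2. The inflammatory cytokine and NF-kB list (median -0.21, adjusted p = 0.0028, and 0.60 with an estimated correlation) held Nfkbia, Tnfaip3 and Ptgs2 at -0.48, -0.31 and -0.45 and, against its direction, the chemokine gene Ccl5 at 0.98. Markers of alveolar type 1 cells (median -0.20, Gprc5a at -0.64) and of alveolar type 2 cells (median -0.14, Il33 at -0.20 and Abca3 at -0.45) passed downward at adjusted p-values of 0.00024 and 0.020 (adjusted p = 0.80 and 0.88 with an estimated correlation). These alveolar lists were also lower in WT 2 than in WT 1 (medians of -0.19 and -0.33) and in SA 2 than in SA 1 (-0.25 and -0.15), and the oxidative phosphorylation list was higher (0.13 and 0.39). With the muscle score as a covariate the alveolar medians were 0.24 and 0.34 and the oxidative phosphorylation list passed camera downward (median -0.16, adjusted p = 0.024). The type 2 list did not pass without SA 2, without WT 1 or with quantile normalization (camera adjusted p = 0.34). Its mean level was 9.70 in WT 1, 9.40 in WT 2, 9.48 in SA 1 and 9.38 in SA 2, so its lower level in SA rests on WT 1. With the muscle score as a covariate neither alveolar list passed (adjusted p = 0.10 and 0.075), nor did the NF-kB (adjusted p = 0.13) and ribosomal lists (adjusted p = 0.25). Adjusted over the list alone, 0 genes of the oxidative phosphorylation, ribosomal and both alveolar lists passed by limma, with 10, 15, 4 and 2 at an unadjusted p under 0.05; in the glucocorticoid list 6 fell, and in the NF-kB list 1 rose (Ccl5) and 2 fell (Nfkbia and Tnfaip3). The other 26 of the 42 lists tested did not pass camera.

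Across all 12850 genes, 40 passed the threshold, 21 higher and 19 lower in SA (limma, adjusted p under 0.05). Several of the largest differences were in genes outside the lists. Rprl3, an RNA of the RNase P family on chromosome 8, rose by 4.94 ± 0.19 (SE; adjusted p = 0.028), from 57 to 70 reads per WT library to 1941 to 2122 per SA library. Nnt, a mitochondrial proton-pumping transhydrogenase on chromosome 13, rose by 1.62 ± 0.08 (adjusted p = 0.029). Tceanc2 on chromosome 4 fell by 2.68 ± 0.11 (adjusted p = 0.028), and Pttg1, the securin gene on chromosome 11, fell by 1.84 ± 0.13 (adjusted p = 0.043). Lrrc8c, Klf7 and Kcnj2 fell by 1.00, 0.98 and 0.90. The processed pseudogene Gm11942, at 5.90 ± 0.12, and Wdfy1, at 1.30 ± 0.06, were picked out after their values were seen. Reads of Rprl3 and Gm11942 can be shared with near-identical copies.

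**Figure D2:**
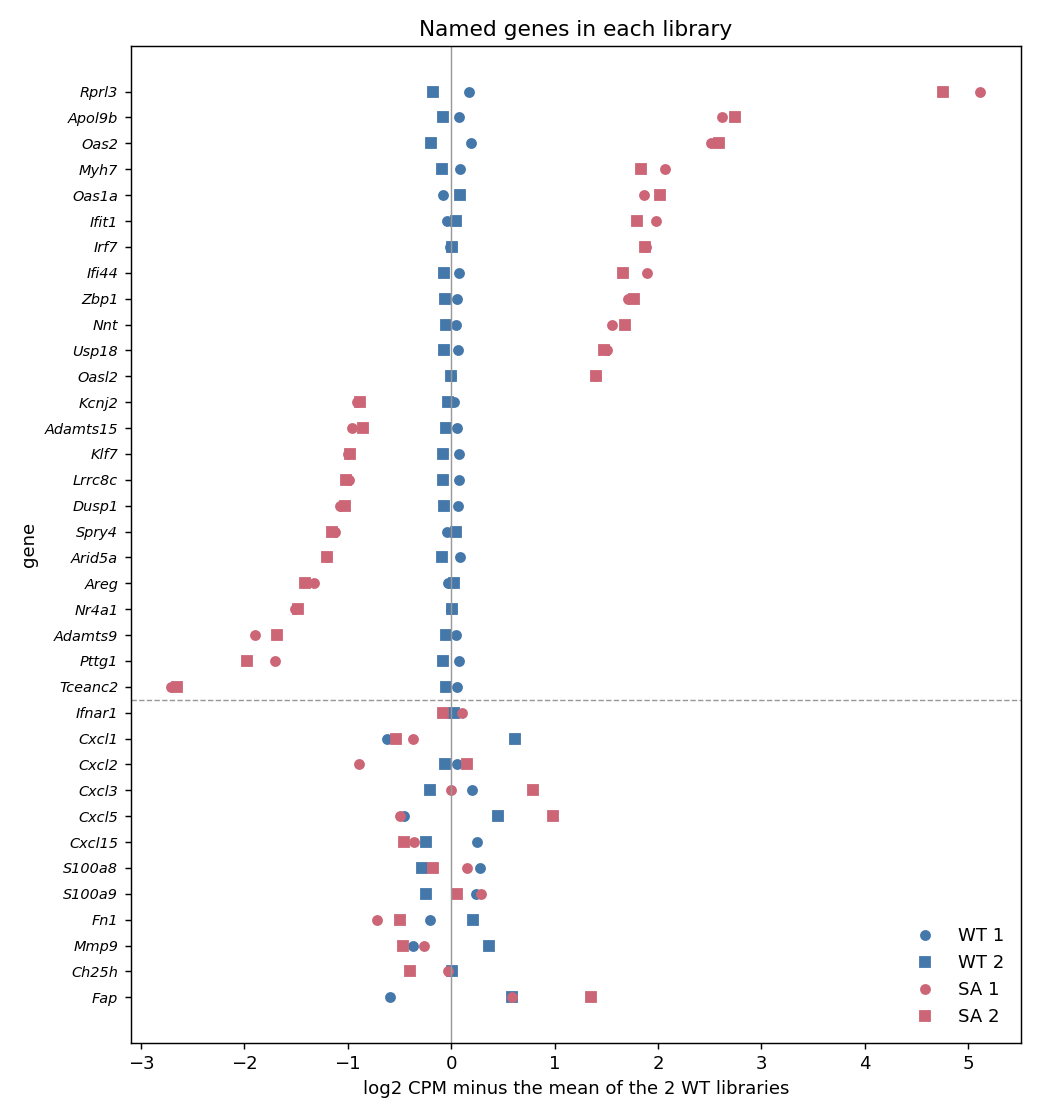
Log2 CPM of each named gene in each library, minus the mean of the 2 WT libraries; blue is WT and red SA, circles are replicate 1 and squares replicate 2. Genes under the dashed line were fixed whatever their result and did not pass it, from Fn1 at -0.60 to Fap at 0.97, with Ifnar1 at 0.01; those above it passed the threshold, from Tceanc2 at -2.68 to Rprl3 at 4.94.

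The number of genes past the threshold is not well determined. At an unadjusted p under 0.05 there were 3508 genes, 2106 higher and 1402 lower, and 318 genes had an adjusted p of at most 0.0502. By limma the count was 0 without SA 1, without SA 2 and without WT 1 (2791, 2284 and 1812 at an unadjusted p under 0.05), and 6 without WT 2. The split of 21 higher and 19 lower became 170 and 280 with median centring and 162 and 224 with voom and median-of-ratios scaling; the median difference of all genes was 0.06. On the first principal component, with 74.1% of the variance, WT 1 lay at -36.9, WT 2 at -5.3, SA 1 at 10.3 and SA 2 at 32.0. WT 2 was nearer to SA 1 than to WT 1 on that component. On the second, with 19.0%, WT 1 lay at 4.5, WT 2 at -18.2, SA 1 at 16.9 and SA 2 at -3.2. There WT 2 was nearer to WT 1 than to SA 1. Over the 12041 genes used, the SD of the log2 differences was 0.346 between WT 2 and SA 1. Between WT 2 and WT 1 it was 0.372. The correlations were 0.9787 and 0.9783, so WT 2 was about as near to SA 1 as to WT 1.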

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

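The tests of carried-over muscle, tissue mix, library depth and immune cell content in this part were chosen after the results were seen. The comparisons between genotypes use the filtered table, and a signal also appeared in genes that the filter left out. Of these, 466 passed the threshold, 410 higher and 56 lower in SA (limma, unfiltered table, with 2213 genes past the threshold in all). This rests on the genes at low levels that enter that fit: with the unfiltered table restricted to a mean of at least 1 log2 CPM, 36 genes passed, 34 of them among the 40 of the filtered table. They include genes of the list for natural killer and cytotoxic lymphocytes, 1 of the 45 fixed lists, which has 1 measured gene in the filtered table and 18 in the unfiltered one. Over those 18 the median difference was 0.85, beside 0.69 for the type II interferon list. Both SA values lay above both WT values in 14 of the 18 and below in 0. Over the 12850 genes of the filtered table they lay above in 4857 and below in 2946. Of the 18, 5 passed the threshold upward in the fit of the unfiltered table. Of these 5, 1, Ccl5, is in the filtered table and did not pass there (limma adjusted p = 0.060). Gzmb, Gzma and Ccl5 differed by 1.48, 0.84 and 0.98 and Ncr1, an NK cell receptor, by 1.29, on 39 to 148 reads per library for Gzmb and 20 to 60 for Ncr1. Over the 7 genes of the list with a mean of at least 1 log2 CPM, 0 passed over all genes by limma (4 adjusted over the list alone).

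The rise of muscle genes in SA is the first pattern weighed. Library depth is argued against, since SA 1 is the shallowest library, yet its muscle genes lay above those of WT 2 by a median of 0.7477, with quartiles of 0.64 and 0.88. A candidate explanation is heart and skeletal muscle tissue taken along with the lung. It predicts that the muscle genes move together within a genotype too. Of the 35, 33 were higher in WT 2 than WT 1 and in SA 2 than SA 1. Myh7, the 1 muscle gene past the threshold over all genes, went against this prediction. It was at 4.14 in WT 1, 3.97 in WT 2, 6.12 in SA 1 and 5.89 in SA 2. The mouse lung holds cardiac muscle in its large veins, so the cardiac list does not name a tissue outside the lung with certainty. That reason does not cover the skeletal muscle list, which had a median difference of 1.19 over 16 genes. An effect of genotype on muscle genes was not tested apart from this and stays open.

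The rise of interferon-induced genes in SA is the second pattern. A different mix of tissue that follows muscle in the SA pieces predicts that the list moves with the muscle genes within WT. Its median for WT 2 minus WT 1 was instead -0.096 (quartiles -0.20 and 0.06). With the muscle score as a covariate, which draws on the same steps within a genotype, its median difference was 1.10. Ciliated cell markers rose by a median of 0.70 from WT 2 to SA 1 but by 0.22 from WT 1 to WT 2. A change of tissue apart from muscle therefore stays open. More monocytes, macrophages or neutrophils in the SA pieces would need their markers to rise about as much as the interferon list's 0.91. The upper quartile over 40 such markers was 0.3244 and their median 0.12. The 19 monocyte and macrophage markers alone had an upper quartile of 0.40 and a median of 0.20. Adjusted over these 19 alone, 2 rose and 1 fell. In the unfiltered table the upper quartiles were 0.31 for dendritic, 0.5177 for T and 0.43 for B cell markers. In the filtered table the 12 measured B cell markers had a median of -0.24 for SA 1 minus WT 2. More NK or plasma cells stay open, as does interferon released by other cells: the plasma cell list had a median of 1.66, but rose by 1.32 from WT 1 to WT 2 and 0.54 from WT 2 to SA 1, and the T cell genes Cd3g, Cd8a and Cd3e, picked out after their values were seen, differed by 0.80, 0.64 and -0.24 in the unfiltered table (adjusted p = 0.021, 0.19 and 0.93 by limma; for Cd3g 0.12 without SA 2). An effect of the genotype is a candidate explanation, as a hypothesis. An exposure or infection shared by the SA mice would give the same values. A difference in strain background, raised further on, could do so too. None of these was tested for the interferon list.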

How the results depend on the processing

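The interferon list kept its direction under all 16 alternatives (median 0.78 to 1.10) and its call under 14. The direction could not turn with the replicate block or the other list tests, which leave the median at 0.91 by construction. With camera at an estimated correlation and in fry the adjusted p-values were 0.60 and 0.052. Those 2 tests left 0 of 16 lists past the threshold (2 and 9 of 42 at an unadjusted p under 0.05). The list count was 27 in the unfiltered table and 17 to 21 otherwise. Under the muscle covariate 8 of the 16 kept their call, 7 lost it and 1 turned direction. The 7 include the cardiac and skeletal muscle lists, whose loss under a muscle score was fixed in advance. The 40 changed genes became 2213 in the unfiltered table, 415 with the stricter filter, 450 with median centring (170 higher, 280 lower), 0 with quantile normalization (3157 at an unadjusted p under 0.05), 1 without a trend, 611 with a robust trend, 3 with a 0.5 CPM pseudocount, and, in alternatives chosen after seeing the data, 268 with voom, 386 with voom and median-of-ratios scaling and 191 with the muscle score as a covariate (35 higher, 156 lower). With 1 library left out, the lone sample being assumed to vary like the other group, it was 0 to 6. Many genes share an adjusted p just above 0.05, so small changes in p move the count; further causes were not tested.

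With the replicate number as a block the count was 3179, and Fn1 and Fap passed (limma adjusted p = 0.0046 and 0.00072). The labels do not say that the numbers pair the mice; the differences WT 1 minus WT 2 and SA 1 minus SA 2 correlated across 12041 genes at r = 0.644, genes not being independent.

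The Ifnar1 difference was -0.0347 with median centring, -0.0108 with quantile normalization, -0.0513 with voom and median-of-ratios scaling, and -0.0815 to 0.11 with 1 library left out. The neutrophil chemokine median was 0.0114 in the unfiltered table and -0.28 to 0.16 with 1 library left out. With 1 library left out, Cxcl1 ranged from -1.07 to 0.17, Cxcl2 from -0.89 to 0.16, Cxcl5 from -0.50 to 0.99, Cxcl15 from -0.65 to -0.16, Fn1 from -0.81 to -0.40, Fap from 0.38 to 1.56, Ch25h from -0.40 to -0.0278, S100a8 from -0.29 to 0.27, S100a9 from -0.0662 to 0.41, Mmp9 from -0.73 to 0.00269 and Ide from -0.70 to 0.18. Cxcl5 was -0.43 with quantile normalization. With the muscle score as a covariate, which leaves 1 residual degree of freedom, Cxcl3 was -0.0235, Cxcl5 -2.25, Cxcl15 0.20, S100a8 0.92, Ch25h 0.20, Fap -1.13, Ptgs2 0.15, Abca3 0.0115, Il1b 0.19 and Pf4 -0.00325, and Fn1 passed at -1.26 (limma adjusted p = 0.034). Fap also passed with a robust trend (adjusted p = 0.016). The cause was not tested. The planned count models on recovered reads, edgeR and DESeq2, were not run. Depth limits Cxcl2, Cxcl3 and Cxcl5, at 3 to 27 reads per library.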

Other observations

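The placement of the 5 genes below on chromosomes was looked up after their values were seen; the tests of Entpd4 and Ide and of the neighbourhood of Ifnar1 were written before their results were seen. The airway, squamous, cartilage and thyroid lists in the next paragraph were written after the muscle genes had been seen, and 5 of the 12 airway gland genes (Bpifa1, Bpifb1, Ltf, Reg3g and Scgb3a1) had values that had been seen before the lists were written.

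Genes of upper airway glands and goblet cells were higher in SA. Over the 7 of them whose values had not been seen before, the median difference in the unfiltered table was 2.99. Both SA values lay above both WT values in 7, as in 4857 of the 12850 genes of the filtered table. Mean levels over the 7 were 0.08 in WT 1, 2.09 in WT 2, 3.64 in SA 1 and 4.12 in SA 2. Over all 12 genes the median was 3.07, and 11 were higher in WT 2 than WT 1 and 8 in SA 2 than SA 1; without WT 1 the medians over the 7 and the 12 were both 1.85. In the unfiltered table all 12 passed the threshold by limma, in a fit that takes in many genes at low levels. In the filtered table, which also holds all 12, 0 passed by limma (6 at an unadjusted p under 0.05). The fixed list of club and secretory cells, which shares genes with this one, had a median of 0.37 over 16 genes and did not pass camera (adjusted p = 0.075). Genes of squamous and basal epithelium had a median of 1.04 over 12, but of 0.02 without WT 1. All 12 were higher in WT 2 than WT 1 and in SA 2 than SA 1, and the groups were separated in 0. Their mean level of 6.08 in WT 2 was above the 5.32 of SA 1. Airway cartilage genes had a median of 1.76 over 12, and of 0.69 without WT 1. Their means were -2.94 in WT 1, -0.83 in WT 2, -0.89 in SA 1 and 0.70 in SA 2. All 12 were higher in WT 2 than WT 1 and in SA 2 than SA 1. Thyroid genes had a median of -0.04 over 6. Adipocyte genes, 1 of the 45 fixed lists, did not pass camera: 15 of 15 were higher in WT 2 than WT 1 and in SA 2 than SA 1, by medians of 2.87 and 1.81. Igha, an immunoglobulin heavy chain gene picked out after its values were seen, differed by 4.76 ± 0.62 (SE; limma adjusted p = 0.0502, just above the threshold); the fixed list of 14 immunoglobulin and plasma cell genes had a median of 1.66 and did not pass camera (adjusted p = 0.051, and 0.80 with an estimated correlation). Its mean level was 2.53 in WT 1, 4.55 in WT 2, 5.28 in SA 1 and 5.33 in SA 2, and its median was 0.77 without WT 1 and -0.19 with the muscle score as a covariate.

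Nnt, Wdfy1, Tceanc2, Gm11942 and Rprl3 differed sharply between the genotypes with little spread within them, which is the third pattern weighed. A flanking segment carried along with the Ifnar1 allele on chromosome 16 would not reach them, since 0 of the 5 genes are on that chromosome. A difference between C57BL/6 substrains may account for Nnt and Wdfy1. It was tested on Entpd4 and Ide, taken beforehand as genes that differ between substrains. Entpd4 differed by -0.80 (limma unadjusted p = 0.022, adjusted p = 0.21) on 20 to 52 reads per library. Its values were 0.78 and 0.62 in WT and -0.42 and 0.21 in SA. Ide differed by -0.26. The smaller of these 2 differences, 0.2591, met neither the bound for such a cause nor the bound against it. Ide could not decide the question, since it varied more within each genotype than between them, at 7.24 and 8.12 in WT and 7.04 and 7.80 in SA. Unlinked genes need not split by genotype among littermates. These 5, on chromosomes 1, 4, 8 and 13, all did. They were picked for differing between the genotypes, so their split was fixed by the choice and decides nothing. Substrain and genotype cannot be told apart without the parents' genotypes. This holds for these genes and for any other difference between the groups, the interferon list included. Shared reads with near-identical copies were not tested.

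Near Ifnar1 itself, 30 of 74 genes within 10 Mb had an unadjusted p under 0.05 (40.5%, against 27.2% of the other genes; two-sided Fisher exact test, p = 0.0128), 18 higher and 12 lower, and 0 passed the adjusted threshold. Because neighbouring genes are not independent, runs of 74 genes elsewhere were counted after this was seen, and 3 of 165 (1.82%) held as many. Among them, Rcan1 and Wrb, picked out after their values were seen, differed by -0.61 and 0.60. A flanking segment carried along with the Ifnar1 allele is a candidate explanation, as a hypothesis; regulation of neighbouring genes by the genotype itself was not tested.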
